A study of Drosophila melanogaster with 6 samples.

How the data were processed

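Whole adult Drosophila melanogaster were profiled on 6 single-colour Affymetrix arrays, 1 for each combination of 3 genotypes and 2 injections. The genotypes were gyc76c[revert], the control, gyc76c[KG03723], a mutant of the receptor guanylate cyclase gene Gyc76C, and spz[rm7], a mutant of the gene for the Toll ligand Spätzle. They are called revert, KG03723 and rm7 here. Flies were injected with phosphate-buffered saline (PBS) or with Staphylococcus saprophyticus, a Gram-positive bacterium, and taken 12 hours later, per the labels. The authors deposited one linear intensity per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version is not given in the sources used here. In the deposited values each array has a 2% trimmed mean of 500, so rescaling the arrays to one trimmed mean changed nothing. Detection calls and scan dates were not used here.

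The table holds 18952 probe sets. After 183 control probe sets were left out, the platform annotation listed 1 gene for 13647, several genes for 402 and none for 4720. Symbols were looked up by gene identifier in a RefSeq gene table of assembly Release 6, which held 13544 of the 13647, and 0 symbols changed. The 5122 probe sets without a single gene were counted separately and not named. For each of 11982 genes the probe set with the highest mean signal was used. Signals under 42.7, the 40th percentile of all values, were set to that floor before the log2 was taken. Where the dimmer array was at the floor, the fold is a bound and is written as "at least". A difference between 2 ratios is written so only where 1 of its 4 arrays was at the floor and a lower signal there would make it larger. Between 58.9% and 61.0% of probe sets were above the floor on each array, and 10105 genes were above it on at least 1 array.

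With 1 array per group there is no replicate spread, so comparisons of 2 arrays give ratios and the number of genes at least 2-fold apart, without a test. A gene list was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size matched on mean signal in 20 bins. These percentiles describe these arrays and treat genes as independent, which they are not. One model was tested, with limma 3.58.1 in R 4.3.3: an additive fit of genotype and treatment over the 6 arrays for the 9540 genes above the floor on at least 3 arrays, with moderated variances following a trend with signal and Benjamini-Hochberg adjustment at 0.05. It has 2 residual degrees of freedom. Its error is the departure from additivity, so a response that differs between genotypes counts as error. Each list of at least 5 measured genes was tested in the same fit with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. With 2 residual degrees of freedom, camera at an estimated correlation has little power. Failing it does not show that a list was unchanged. The number of arrays limits the precision of every value. Nothing in the labels says how many flies, or of which sex, went into an array.

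Gene lists and the rule for naming genes were fixed before the data were examined. The rule takes Gyc76C and spz, then the 6 highest and 6 lowest genes above the floor on all arrays of a comparison plus the 3 largest bounds, the 6 highest and 6 lowest genes past the threshold of the fit, the 4 members of a described list with the largest change, and every Toll- and IMD-responsive peptide. The alternatives were quantile and cyclic loess normalization, floors at the 20th and 60th percentile, a pseudocount in place of the floor, the mean over a gene's probe sets, a 3-fold threshold, fits without each genotype, without the genotype term or without the variance trend. After the data were seen, 3 kinds of alternative were added: a fit with the testis list mean as a covariate, fits without each array, and counts without genes that follow the testis list.

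The procedures were tested on simulated data of 9540 genes with 200 changed genes and noise taken from the fit. In a simulated comparison of 2 arrays, 44% of genes changed by 1 on the log2 scale and 92% of those changed by 2 were at least 2-fold apart in the right direction, and so were 1.05% of unchanged genes in either direction. The simulated treatment effect over 3 genotypes was recovered for 72% of genes changed by 1 and 92% of those changed by 2, with 18 unchanged genes called. For a genotype effect the shares were 60% and 92%, with 8 unchanged genes called. The simulation gave each gene its moderated variance, independent noise and the same effect on every changed array. Real responses can differ between genotypes, so these shares may overstate what the real fit recovers.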

Results

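The series measured gene expression in whole adult flies of 3 genotypes, 12 hours after injection of PBS or of Staphylococcus saprophyticus. There was 1 array for each of the 6 combinations, so ratios between single arrays carry no error and no p-value. The highest signal per array lay between 30455 and 41453. Floored log2 signals of array pairs correlated with a Pearson r of 0.946 to 0.985 across the 9540 genes above the floor on at least 3 arrays. The 3'/5' signal ratios of the actin, GAPDH and eIF-4a controls were all highest on the rm7 bacteria array (2.81, 2.68 and 6.61) and all lowest on the revert bacteria array (2.29, 1.99 and 5.66).

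The mutated genes were looked at first. All 3 probe sets of Gyc76C are annotated jointly with a second gene, CG42637, so their signal cannot be assigned to Gyc76C alone. The brightest read 2092 in revert and 1085 in KG03723 after PBS, a ratio of 0.519, and 2004 and 1234 after bacteria, a ratio of 0.616. In rm7 it read 1523 after PBS and 1583 after bacteria. The transcript of spz itself was near the control level in rm7, at 951 against 1059 after PBS and 813 against 1122 after bacteria. Nothing in the labels says that the rm7 lesion lowers the transcript, so this level does not check the label.

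The response of control flies to the bacterium was read from the revert arrays. Effector peptides of the Toll pathway were higher after bacteria. All 11 measured members, of 30 listed, lay above 0, with a median log2 ratio of 0.69, above all 10000 random lists. BomT2 was at 4226 after PBS and 11515 after bacteria (log2 1.45), BomBc2 at 9958 and 26637 (1.42), and BomBc3 at 8977 and 20235 (1.17). The antifungal peptide gene Drs was at 20396 and 27602 (0.44). Of the 20 measured Toll pathway components, 4 were at least 2-fold higher. SPE, the protease that cleaves Spätzle, was at 2259 and 6745 (1.58), the protease gene Hayan at 133 and 407 (1.62), the serpin gene nec at 1362 and 3705 (1.44) and spirit at 103 and 224 (1.12). The median of all 20 was 0.08, with 13 above 0 and 7 below. Over the 3 genotypes the list did not pass camera (adjusted p = 0.143 with a preset and 0.813 with an estimated correlation).

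Further genes at the top of the revert comparison were CG33462 (102 after PBS, 743 after bacteria), Lst, which encodes the hormone limostatin (362 and 1580), CG11842 (294 and 1262), CG6553, CG30026 and CG9616. CG30091 was at least 7.83-fold higher and CG18557 at least 4.67-fold higher. Of 13 listed IMD-responsive peptide genes only 5 were measured, so every value for this list describes a part of it. These 5 had a median of 0.75, with CecB at 0.89, Def at 0.78, edin at 0.75, DptB at 0.36 and AttD at 0.24. At the low end stood Lsp2, which encodes a storage protein, 11.2-fold lower (2431 and 217.5), the odorant-binding protein gene Obp99b, 7.63-fold lower (5447 and 714), Srr, Cyt-b5-r, Sodh1 and Cyp4e3. CG13040 was at least 3.77-fold lower.

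In all, 59 genes were at least 2-fold higher and 346 at least 2-fold lower in revert after bacteria. Quantile normalization gave 82 and 159 and cyclic loess 80 and 190. Testis genes lay among the lower ones, with a list median of -0.91 over 21 genes, below all random lists. The sperm chromatin protein gene ProtB was at 464 after PBS and 175 after bacteria (-1.41), followed by c-cup (-1.19), Mst84Da (-1.05) and Mst98Cb (-1.03). Male accessory gland genes had a median of -0.63 over 19 genes, with Acp53C14c at -1.25, Sems at -1.01, Acp26Aa at -0.91 and Acp76A at -0.84. Without the 478 genes whose profile over the 6 arrays follows the testis list, 195 genes were at least 2-fold lower.

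In KG03723 the Toll-responsive peptides were also higher after bacteria, with all 11 above 0 and a median of 0.86, above all random lists. BomS2 was at 4168 after PBS and 18727 after bacteria (4.49-fold), against 14956 and 29100 in revert. BomBc3 followed at 1.64, BomT2 at 1.28, BomT3 at 1.17 and BomS5 at 1.13. Diedel, a secreted immune-regulated protein gene, was at 450 and 4256 (9.46-fold), and CG4757 at 1907 and 13895 (7.29-fold). CG33462, CG30091 and CG18563 were 6.95-fold, 5.89-fold and 5.04-fold higher, and NimB1 and CG32100 were at least 2.37-fold and 2.33-fold higher. The IMD-responsive list stood at 0.12, at the 78.6th percentile of random lists. In it Def read 2068 and 2253, against 4475 and 7683 in revert, and edin 5083 and 4926, against 4656 and 7832 in revert.

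Genes at the low end in KG03723 were Lsp2 (5719 after PBS and 362 after bacteria, 15.8-fold), CG32444, the sorbitol dehydrogenase gene Sodh1 (5.76-fold), CG3699, Obp99a and the cytochrome P450 gene Cyp6w1 (4.39-fold). CG30457 was at least 2.41-fold lower. Plasmatocyte markers, the genes typical of the phagocytic blood cells, had a median of -0.54, below all random lists, with 14 of 16 below 0. Pxn, a peroxidase of the extracellular matrix, read 281 after PBS and 118 after bacteria (-1.25), the scavenger receptor gene Sr-CI 203 and 103 (-0.97), the collagen gene Col4a1 2288 and 1319 (-0.79) and Hml 376.5 and 241 (-0.64). The same list had a median of -0.04 in revert and 0.22 in rm7, and the differences between genotypes were not tested. Several list members encode basement membrane proteins that fat body cells also make. Fat body metabolism genes had a median of -0.38 over 28 genes, led by CG6283 (-0.97), the acetyl-CoA carboxylase gene ACC (-0.92), CG8093 (-0.90) and Lip4 (-0.86), and detoxification genes one of -0.30 over 44. In total 48 genes were at least 2-fold higher and 87 lower. The testis list had a median of -0.04 here.

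In rm7 all 11 Toll-responsive peptides were again above 0, with a median of 0.56, but 0 of them reached 2-fold, against 3 in revert and 5 in KG03723. The difference between genotypes was not tested. BomBc3 read 765 after PBS and 1123 after bacteria, and BomT2 1572 and 2061. SPE stood at 835 and 956.5 (0.20), nec at 689 and 731 (0.09) and Hayan at 124 and 132 (0.09). CG4757 read 82.3 and 124.5. The IMD-responsive list had a median of 0.84, above all random lists. AttD, which encodes an attacin, was at 114 and 611, 5.37-fold higher, and the cecropin gene CecB at 157 and 592, 3.76-fold higher. Among genes above the floor on both arrays they led the comparison, ahead of CG32628, CG13947, CG11756 and CG13044.

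The low end of the rm7 comparison held genes of the eggshell. Cp16 was at 8507 after PBS and 660 after bacteria (12.9-fold lower), Cp19 at 7565 and 621.5 (12.2-fold), Femcoat at 567 and 52.6 (10.8-fold) and Cp18 at 5128 and 1330 (3.86-fold). CG13083 was 12.8-fold lower and Muc12Ea 3.32-fold lower, with CG13084, CG15571 and CG31926 at least 6.28-fold, 5.77-fold and 4.06-fold lower. Of the 17 measured chorion and vitelline membrane genes, 13 lay below 0, with a median of -0.33. The ovary germline list had a median of -0.27. Testis genes had a median of 0.58, accessory gland genes of 0.49 and muscle genes of 0.40, all above all random lists. In the muscle list TpnC73F stood at 1.10, Act88F at 1.04, sls at 0.64 and Mlc1 at 0.58. In total 63 genes were at least 2-fold higher and 33 lower, a balance that turned to 37 and 45 with quantile normalization and 40 and 43 with cyclic loess. Both directions together gave 96 genes, against 135 in KG03723 and 405 in revert. In the simulation of 9540 genes, 98 of those left unchanged were at least 2-fold apart between 2 arrays. That count cannot judge these totals, which cover 10105 genes. The simulated noise comes from the additive fit and so includes responses that differ between genotypes.

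**Figure D1:**
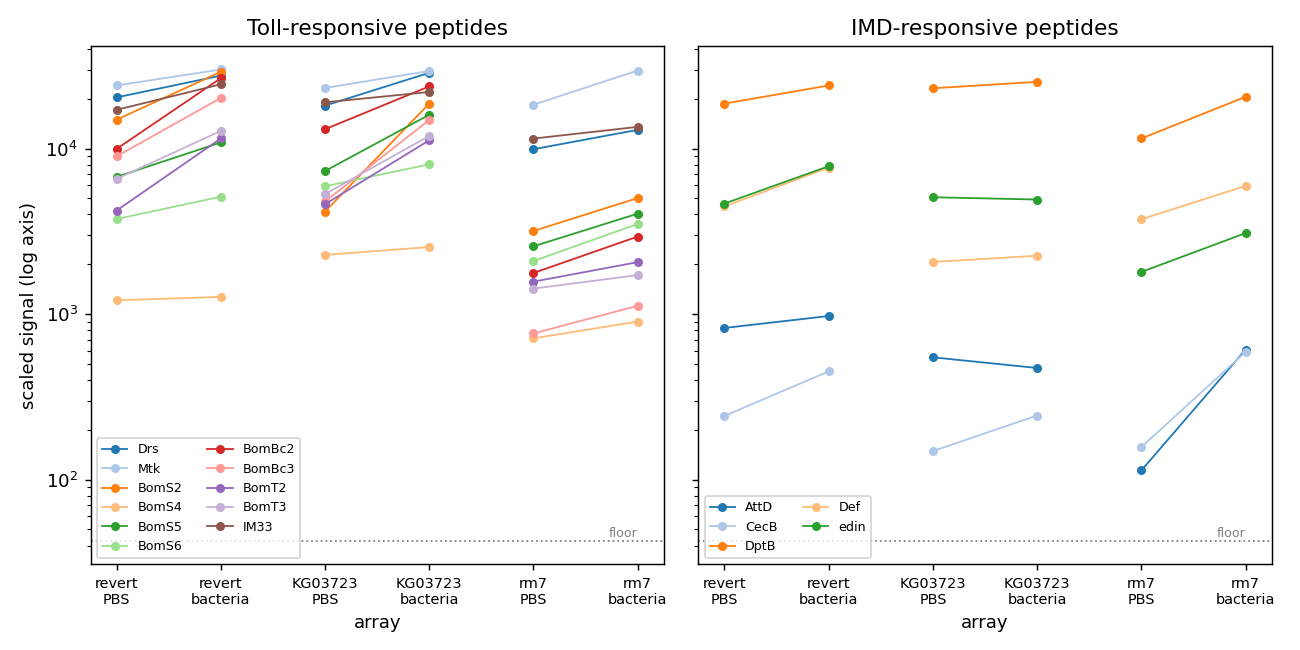
Scaled signal on a log axis of 11 Toll-responsive (left) and 5 IMD-responsive (right) peptide genes on the 6 arrays; each point is 1 array, lines join the PBS and bacteria arrays of a genotype, and the dotted line is the floor of 42.7. Most Toll-responsive peptides sit lower in rm7 than in the other genotypes on both arrays, while AttD and CecB show their steepest lines in rm7.

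**Figure D2:**
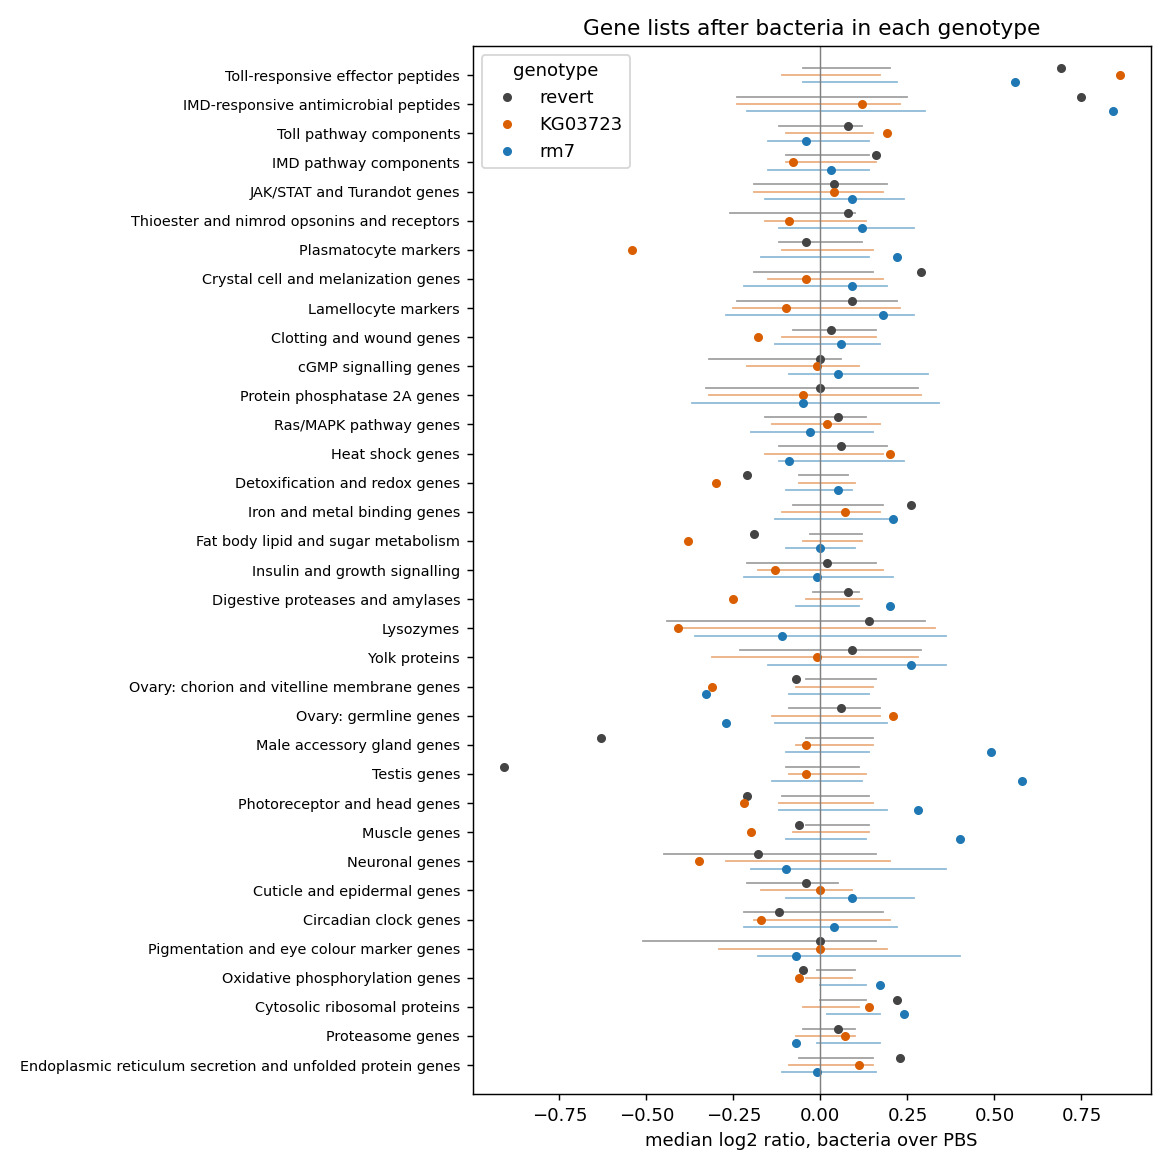
Median log2 ratio of bacteria over PBS for each gene list in revert (grey), KG03723 (orange) and rm7 (blue); points are list medians and thin lines the central range (all but the outer 2.5% on each side) of the medians of random lists. The Toll-responsive list lies at 0.69, 0.86 and 0.56, and the testis list at -0.91, -0.04 and 0.58.

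The shared effect of the bacterium over the 3 genotypes was tested with the additive limma fit, 3 arrays against 3. After adjustment 0 genes were higher and 0 lower. At an unadjusted p under 0.05 there were 347 genes, where 477 of the 9540 are expected by chance, and the smallest adjusted p was 0.321. The top of the ranking held Fst (0.83), Obp99b (-2.13), BomS5 (0.83 ± 0.11 SE, adjusted p = 0.459) and BomBc2 (SE 0.14, adjusted p = 0.459). Adjusted over the list alone, 10 of the 11 Toll-responsive peptides and 4 of the 5 IMD-responsive peptides passed as higher, against 0 of each over all genes. The camera test with a preset correlation placed the Toll-responsive list higher than other genes (adjusted p = 1.35e-27, median log2 0.80), and likewise the cytosolic ribosomal proteins (adjusted p = 7.62e-23, median 0.20) and the IMD-responsive list (adjusted p = 1.8e-08, median 0.52). With an estimated correlation the adjusted p was 0.228, 0.618 and 0.618, and 0 of 32 lists passed, against 13 with the preset one. With fry, 0 of 32 lists passed in a common direction for bacteria, KG03723 or rm7, and 0, 7 and 17 passed when members may change in either direction. Without the revert arrays the fit called 20 genes higher and 26 lower, and the 4 arrays left then come from the 2 mutants. Leaving out the rm7 PBS array or the rm7 bacteria array gave 4 higher and 4 lower each.

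**Figure D3:**
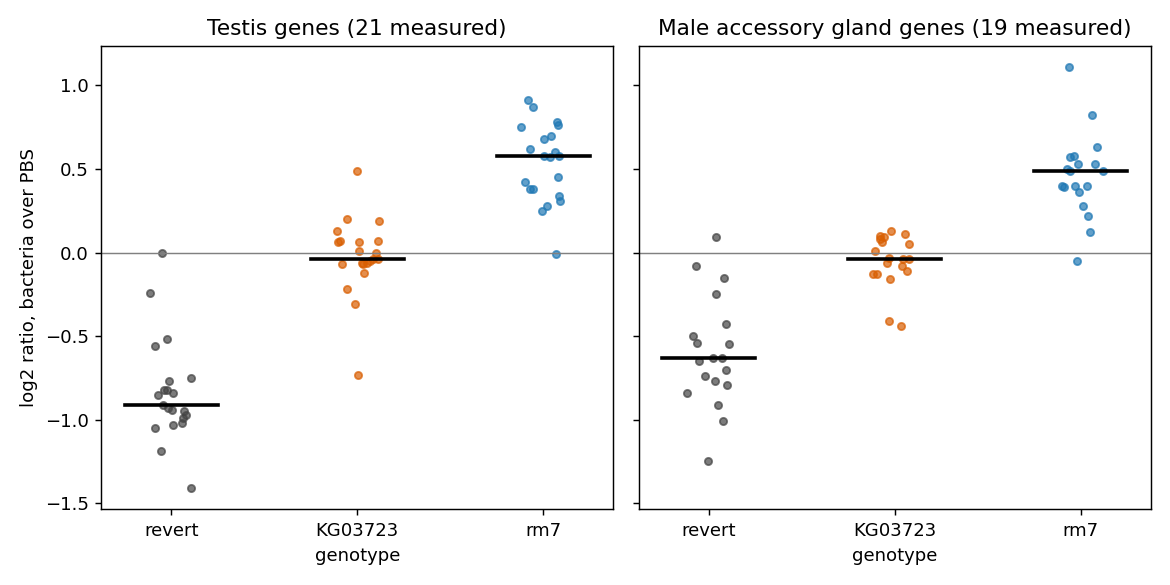
Log2 ratio of bacteria over PBS for each measured testis gene (left) and male accessory gland gene (right) in the 3 genotypes; each point is a gene, horizontal bars are list medians, and the horizontal position within a genotype carries no meaning. Testis genes lie lower in revert (median -0.91), near 0 in KG03723 (-0.04) and higher in rm7 (0.58).

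Differences between KG03723 and revert were read from both arrays of each genotype. In the limma fit 65 genes were higher and 66 lower in KG03723. The lowest was cnk, which encodes a scaffold of the Ras and Raf cascade. It read 874 and 950 in revert against 21.0 and 26.7, under the floor, in KG03723 (log2 -4.41 ± 0.20 SE, limma adjusted p = 0.000922), and 1083 and 965 in rm7. Pepck2, a phosphoenolpyruvate carboxykinase gene, was lower (-3.49 ± 0.21, limma adjusted p = 0.00103), as were the peroxiredoxin gene Prx6c (-3.24), the digestive protease gene Jon44E (-2.90), CG6788 (-2.87) and CG2772 (-2.65). Higher genes were Srg2 (4.05 ± 0.36, limma adjusted p = 0.00509), the lysozyme gene LysX (3.50), at 12524 and 11235 against 1051 and 1047, the antiviral factor gene Vago (3.46), the protease gene Ser12 (3.02), CG10943 (2.94) and CG17234 (2.88). Several of these differences were not particular to KG03723. In rm7 Prx6c read 304 and 216, against 2892 and 1922 in revert, and Jon44E 627 and 722, against 1940 and 1839. CG6788 was also lower in rm7 than in revert after both injections, and Srg2, Vago, Ser12 and CG10943 were higher. Pepck2 and CG2772 in rm7 were nearer to revert than to KG03723, CG17234 was mixed, and LysX was lower in rm7 than in revert. Signals of cnk and CG2772 in KG03723 and of Ser12 in revert were under the floor on both arrays, and that of CG6788 in KG03723 on the bacteria array, so those fitted sizes depend on the floor. After PBS, cnk was at least 20.4-fold and CG2772 at least 6.01-fold lower, and Ser12 at least 8.81-fold higher. The counts rest on few arrays: 15 were higher and 38 lower without the KG03723 PBS array, 39 lower without the KG03723 bacteria array, 182 higher without the revert PBS array, and 118 and 112 without the revert bacteria array. Without the variance trend 17 were higher and 15 lower.

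After PBS alone, 174 genes were at least 2-fold higher in KG03723 than in revert and 134 lower. Besides the genes above, CG8353 was 7.83-fold higher, Diedel 12.6-fold lower (5690 in revert and 450 in KG03723) and CG32284 7.51-fold lower. Toll-responsive peptides had a median of 0.12, with BomS2 the 1 member at least 2-fold lower. The IMD-responsive list stood at -0.59, at the 0.05th percentile of random lists, with 3 of 5 members below 0, and at -0.89 after bacteria, with 4 of 5 below 0. Over both treatments camera gave it an adjusted p of 0.017 with the preset and 0.967 with an estimated correlation, and 1 of the 5 passed as lower over all genes. The digestive protease and amylase list had a median of -0.15 after PBS, and the chorion and vitelline membrane list one of 0.71. In the fit over both treatments the digestive list passed camera with the preset correlation (median -0.33, adjusted p = 1.06e-06, and adjusted p = 0.967 with an estimated correlation). In it 2 of 39 genes were higher and 9 lower in the limma fit over all genes, and 4 and 18 adjusted over the list alone. In rm7, 2 of the 39 were higher than in revert and 12 lower over all genes, so this is not particular to KG03723. Chorion and vitelline membrane genes were placed higher in the same fit (median 0.53, adjusted p = 2.88e-09 with the preset and 0.967 with an estimated correlation), with 4 of 17 higher over all genes and 10 adjusted over the list alone. After bacteria 219 genes were at least 2-fold higher and 125 lower, or 152 and 146 with quantile normalization. The testis list had a median of -0.23 after PBS and 0.64 after bacteria, and the muscle list of -0.21 and -0.25, with all 19 muscle genes below 0 after bacteria. The revert arrays are shared with the rm7 comparisons, so the overlap of the genes called in the 2 mutants was not counted.

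Differences between rm7 and revert were larger in number, with 249 genes higher and 286 lower in the limma fit. The Toll-responsive list was 1.39 lower on the log2 scale in the median after PBS and had a median of -1.43 after bacteria, below all random lists in both, with 7 of 11 members at least 2-fold lower each time. In the fit 10 of the 11 passed as lower over all genes, and camera with the preset correlation gave an adjusted p of 1.01e-15. With an estimated correlation of -0.00466 the adjusted p was 0.399, and with fry 0.0522. BomBc3 was at 8977 in revert and 765 in rm7 after PBS, and at 20235 and 1123 after bacteria. Mtk read 24081 in revert and 18424 in rm7 after PBS, and was close to the control level after bacteria, at 30062 and 29644. The highest signals on those bacteria arrays were 37347 and 41453. Whether signals this high were compressed was not tested. The IMD-responsive list was lower in rm7 as well, with a median of -0.70 after PBS and -0.37 after bacteria, at the 0.56th and 2.22th percentile of random lists. AttD read 825 in revert and 114 in rm7 after PBS, and 974 and 611 after bacteria. In the fit 1 of the 5 genes passed as lower over all genes, and camera gave an adjusted p of 0.00655 with the preset correlation and 0.99 with an estimated one.

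The lowest gene in rm7 was CG4757, at 5095 and 18036 in revert against 82.3 and 124.5 (log2 -6.56 ± 0.45 SE, limma adjusted p = 0.000696). CG33229 (-5.09), Diedel (-5.05 ± 0.56, limma adjusted p = 0.00408), CG40191 (-4.92), Cyp12d1-d (-4.62) and the drosomycin-like gene Drsl2 (-4.29) followed. Drsl3 was 16.8-fold lower after PBS. The highest were CG13813 (4.66 ± 0.31, limma adjusted p = 0.000644), the odorant-binding protein gene Obp51a (4.29), CG43085 (4.14), CG7900 (3.89), Ser12 (3.84) and CG11598 (3.73), and after PBS Pxt was 13.7-fold and CG6296 11.1-fold higher. LysX was at least 24.6-fold lower after PBS. Cyp12d1-d and Drsl2 in rm7 and Ser12 and CG43085 in revert were under the floor on both arrays, and CG7900 and CG11598 in revert on the bacteria array, so their fitted sizes depend on the floor. After PBS, Cyp12d1-d was at least 31.9-fold lower and CG43085 at least 25.2-fold higher. Without the rm7 PBS array 144 genes were higher and 190 lower, and without the rm7 bacteria array 72 and 162. In total 254 genes were at least 2-fold higher and 420 lower after PBS, and 548 and 290 after bacteria, where quantile normalization gave 382 and 353. Testis and accessory gland lists had medians of -0.65 and -0.88 after PBS and 0.76 and 0.20 after bacteria, and the muscle list of -0.52 and 0.08.

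Whether the response depended on genotype was read as the difference between 2 log2 ratios over 4 arrays, without a test. The Toll-responsive list had a median of 0.09 for KG03723 minus revert, with 7 of 11 genes above 0, at the 98.45th percentile of random lists. For rm7 minus revert its median was -0.28, with 8 of 11 below 0, at the 0.11th percentile of random lists. The IMD-responsive list had medians of -0.45, with 5 of 5 below 0, and 0.47, with 4 of 5 above 0, at the 0.13th and 98.29th percentile. For KG03723 minus revert, 401 genes were at least 2-fold higher and 110 lower, with 255 and 168 under quantile normalization and 249 higher without the genes that follow the testis list. Among genes above the floor on all 4 arrays the 6 highest were CG12983 (1.98), sun (1.95), CG13693, ProtB (1.89), the cilium gene Tektin-A (1.82) and CG5122, and the lowest CG13063 (-2.13), CG10140, Doc1 (-1.81), CG12998, CG3699 and CG9555. With 1 of the 4 arrays at the floor, CG6785 was at least 4.06-fold and CG42383 at least 3.70-fold higher, and CG15674 at least 3.71-fold lower. For rm7 minus revert, 1089 genes were higher and 104 lower, with 741 and 227 under quantile normalization and 642 higher without the genes that follow the testis list. Above the floor on all 4 arrays, the highest were dbf (2.55), Lsp2 (2.47), CG2209, Mzt1 (2.41), Acp53C14c (2.36) and CG31909, and the lowest Cp19 (-3.61), Cp16 (-3.57), CG13083 (-3.55), Femcoat (-3.03), Muc12Ea and CG31661. With 1 array at the floor, CG32628, lectin-21Ca and CG13040 were at least 6.44-fold, 5.98-fold and 5.77-fold higher. Genes at the floor on more of the 4 arrays were not ranked, such as CG18557 for KG03723 and CG30091 and CG33462 for rm7, both under the floor on the 2 rm7 arrays. Lsp2 was 11.2-fold lower after bacteria in revert, while in rm7 it read 1583 after PBS and 787 after bacteria.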

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

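The tests on eggshell genes were chosen after the result was seen, and the other tests in this part were set before their values were known. That the quartiles, and not the median alone, must lie past the value an explanation needs before it is argued against was added after the values were seen. Several results pointed in opposite directions between genotypes after bacteria; with 1 array per group these differences were not tested. The testis list had a median log2 ratio of -0.91 in revert and 0.58 in rm7, and the male accessory gland list -0.63 and 0.49. Single genes of this kind were Acp53C14c (-1.25 and 1.11), CG2209 (-1.13 and 1.32), CG31909 (-1.09 and 1.28) and CG32628 (-1.04 and 1.64, the first a bound because the revert bacteria array was under the floor). Between KG03723 and rm7, plasmatocyte markers stood at -0.54 and 0.22, digestive proteases and amylases at -0.25 and 0.20, muscle genes at -0.20 and 0.40 and ovary germline genes at 0.21 and -0.27. Photoreceptor and head genes had medians of -0.21 in revert, -0.22 in KG03723 and 0.28 in rm7. CG43085 was at 1.30 in KG03723 and -1.02 in rm7, Cp15 at 1.5 and -1.46, Cp18 at 1.52 and -1.95 and Muc12Ea at 1.49 and -1.73.

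Among probe sets without a single annotated gene, which the comparisons above leave out, 19 were at least 2-fold higher after bacteria than after PBS in revert, 17 in KG03723 and 11 in rm7. The leading one, a probe set annotated with 2 genes, had log2 ratios of 4.33 in revert, 5.06 in KG03723 and 0.03 in rm7, and read 433.5 and 8707, 219 and 7284, and 84.0 and 85.7. The ratio in KG03723 exceeds that of every named gene in the same comparison.

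The first pattern weighed is the excess of genes lower after bacteria in revert, 346 against 59 higher. A response to the bacterium common to all genotypes is argued against, since these 346 genes had a median log2 ratio of -0.06 in KG03723, with quartiles of -0.27 and 0.10. A shift of the array that depends on signal level stays open: 2102 other genes in the same signal range had a median of -0.06 in revert, but with quartiles of -0.41 and 0.15, and quantile normalization lowered the count to 159 and cyclic loess to 190. Less RNA from male tissue in the revert bacteria array, such as from fewer males among the flies, is a candidate explanation. Without testis and accessory gland list members, 339 of the genes had a median of 0.42 in rm7, and 84.7% lay above 0. Testis genes were also higher there after bacteria. The rm7 values do not favour male tissue over a level-dependent shift, which was checked in revert only. From PBS to bacteria the median signal of the array fell from 115.9 to 95.2 in revert and rose from 103.5 to 115.7 in rm7. The 3'/5' control ratios run the same way, all lowest on the revert bacteria array and all highest on the rm7 bacteria array. RNA quality was therefore not separated from a change in male RNA, and neither was a response of male tissue that differs with genotype.

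The second pattern is the low level of late eggshell genes in rm7 after bacteria. A smaller share of ovary RNA on that array is argued against as the only source of that low level. The ovary germline list was lower too, with 10 of 11 genes below 0, at the 0.02th percentile of random lists. Its median of -0.27, with quartiles of -0.37 and -0.11, was far from the median of -2.78 of Cp15, Cp16, Cp18 and Cp19. A small decrease in ovary RNA beside another cause stays open. A different stage of the egg chambers between fly collections may account for the low late genes. In rm7 the earlier chorion genes Cp36, Cp38 and Cp7Fc had a median of -0.49, with quartiles of -0.67 and 0.04. In KG03723 the 4 late genes also moved apart from the earlier ones, by 1.70 in the median and in the other direction. In revert the late genes had a median of -0.06 and the earlier ones of -0.15. An effect of infection on late oogenesis in rm7 stays open as the biological explanation.

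The third pattern is the number of genes called between genotypes. If a chromosome segment linked to the mutation carried them, they could be expected near the mutated gene. Of the 200 tested genes nearest to Gyc76C, 1 was called in KG03723, a share 0.358 times that of the other genes (Fisher's exact test, two-sided, p = 0.53). Of the 200 nearest to spz, 12 were called in rm7, 1.07 times the share elsewhere (Fisher's exact test, two-sided, p = 0.756). Both values argue against a linked segment of that size as the source of most calls; differences elsewhere in the genetic background, and effects of the mutations, were not separated.

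The fit of the bacterial effect over 3 genotypes could not be set against chance by regrouping, since 6 arrays split 3 against 3 in 10 ways. In plain fits without a genotype term the real split gave 0 genes and the highest other split gave 1.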

How the results depend on the processing

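The fit with the testis list mean, the fits without single arrays and the counts without genes following the testis list were chosen after seeing the data. Signals as deposited gave the same values as the rescaled ones. All 12 list medians checked (Toll-responsive, IMD-responsive, testis and plasmatocyte lists) stayed within a factor of 1.5 under every scaling, floor and probe set alternative. Of 105 named gene values 68 moved by more than 1.5-fold under at least 1 alternative and 0 changed sign. The genotype term of the fit pairs the PBS and bacteria arrays of each genotype; without it bacteria against PBS also called 0 and 0 genes. The floor sets how many dim genes can be 2-fold apart.

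Counts below are genes higher and then lower. With the floor at the 20th percentile, bacteria against PBS gave 257 and 645 in revert, 206 and 368 in KG03723 and 368 and 256 in rm7. KG03723 against revert gave 406 and 316 after PBS and 517 and 388 after bacteria, rm7 against revert 547 and 684, then 999 and 486, and the response differences 794 and 510 for KG03723 and 1647 and 444 for rm7. With the floor at the 60th percentile the values in the same order were 30 and 76, 26 and 50, 10 and 11, 90 and 67, 46 and 64, 114 and 188, 177 and 176, 73 and 19, and 305 and 35. With a 3-fold threshold they were 15 and 17, 9 and 16, 4 and 10, 48 and 41, 31 and 39, 81 and 118, 130 and 136, 27 and 11, and 272 and 32, fewer by construction. With the pseudocount, bacteria against PBS gave 212 higher in revert, 171 and 312 in KG03723 and 266 and 210 in rm7, KG03723 against revert 345 and 261 after PBS and 404 and 327 after bacteria, rm7 against revert 486 higher after PBS and 460 lower after bacteria, and the response differences 636 and 469 for KG03723 and 411 lower for rm7. Quantile normalization gave 159 lower in revert, 37 higher in rm7, response differences of 255 and 168 for KG03723 and 227 lower for rm7. Cyclic loess gave 190 lower in revert, 40 higher in rm7, and 168 and 211 lower in the response differences. Without genes following the testis list, 195 were lower in revert and 249 and 642 higher in the response differences, fewer by construction. The cause of the movements under normalization was not tested.

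In the limma fit, bacteria against PBS called 0 and 0 genes; it called 20 and 26 without genotype revert, 2 lower without genotype rm7, and 17 and 9 with the testis list mean as a covariate. That covariate gave 141 and 156 for KG03723 and 431 and 440 for rm7. The mean over probe sets gave 33 and 42 for KG03723. Without the variance trend the counts were 17 and 15 for KG03723 and 130 and 155 for rm7. Leaving out each array in turn gave 0 to 20 higher and 0 to 26 lower for bacteria, 15 to 182 and 38 to 112 for KG03723, and 72 to 302 and 162 to 317 for rm7. In these the lone array of a genotype is assumed to vary like the others. The cause of these changes was not tested, except that fewer arrays enter the fits without an array or genotype.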

Other observations

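Other gene lists were read in the same way after bacteria. Cytosolic ribosomal protein genes had median log2 ratios of 0.22 in revert, 0.14 in KG03723 and 0.24 in rm7 over 42 genes, with 34, 40 and 39 of them above 0. Iron and metal binding genes stood at 0.26, 0.07 and 0.21 over 11 genes, and genes of endoplasmic reticulum secretion at 0.23, 0.11 and -0.01 over 17. The crystal cell and melanization list was at 0.29 in revert, at the 99.99th percentile of random lists, against -0.04 in KG03723 and 0.09 in rm7. Oxidative phosphorylation genes were at -0.05, -0.06 and 0.17 over 73 genes. These differences between genotypes were not tested. Over the 3 genotypes, camera with the preset correlation gave an adjusted p of 7.62e-23 for the ribosomal list, 1.97e-06 for the iron list, 2.11e-05 for the secretion list, 0.0431 for the crystal cell list and 0.197 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.618, 0.527, 0.618, 0.618 and 0.846.

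In rm7 the iron and metal binding list passed camera with the preset correlation as lower than in revert (median -0.37, adjusted p = 1.79e-05, and adjusted p = 0.597 with an estimated correlation and 0.159 with fry), with 2 of 11 genes lower in the limma fit. In KG03723 it did not pass (camera adjusted p = 0.06 with the preset correlation), with 0 of 11 lower. Adjusted over the list alone, 4 of the 11 were lower in each mutant, so this list does not separate KG03723 from rm7. The metallothionein genes MtnD and MtnC read 407 and 1963 in rm7 after PBS, against 4424 and 8695 in revert. The Turandot gene TotC read 5294 in rm7 and 25098 in revert after PBS, and TotB 14.8 and 174.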
